A study of Homo sapiens with 22 samples.

How the data were processed

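RNA from human cell lines had been hybridized to 22 Agilent 2-colour arrays, with the sample in Cy5 and a reference RNA in Cy3. Per the labels, the reference pooled 20 cell lines and 100 ng of total RNA was used per array. The BEAS-2B and SK-LC-3 arrays made up 16 of the 22: each line, with a control construct or a MYC construct, was sampled at 0, 12, 24 and 48 h of doxycycline at 5 µg/mL, with 1 array per line, construct and hour. The other 6 arrays held NCI-H2009 cells given miR-342-3p or a negative control (NC) RNA, with 3 numbered samples each. The arrays lay on 4 slides: one for each MYC line, one with NCI-H2009 samples 1 and 2 of both arms, and one with sample 3 of both arms. On the MYC slides the control arrays lay in row 1 and the MYC arrays in row 2, so that construct and slide row cannot be separated. Slide was a part of every line-by-hour term of the MYC fits.

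The scanner files deposited by the authors hold raw signals of each spot as intensity in arbitrary units, and, per the file headers, a log10 ratio of Cy5 to Cy3 after the scanner software's background subtraction and dye normalization. The deposited series matrix holds values on the log2 scale. Array by array these correlated with the log10 ratio, converted to log2, at r of 0.860 to 1.00 across probes with slopes near 1 and the same direction, and their medians lay between -0.119 and 0.124.

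All fits used the raw median signals. Background was corrected by normexp with an offset of 50, log2(Cy5/Cy3) was loess-normalized within each array in limma 3.58.1, control spots were removed, spots called non-uniform or population outliers were dropped, and spots of the same probe were averaged. A probe was kept for a fit if its Cy5 signal was well above background by the software's own call on at least 3 arrays of that fit. Within a fit, 63 probes were lost to outlier spots. Each gene was represented by its brightest kept probe. Computation ran in R 4.3.3, with the package data.table in version 1.17.8.

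Probe coordinates are those of the files, on hg19. Gene names came from the RefSeq table of assembly GRCh38.p14, used for names alone. Of 42405 probes of transcripts, 26244 were named by accession, 3474 by symbol and 457 by an older symbol, 5231 kept the name given in the files, and 6999 had no name, which left 25394 distinct names. Probes with no name were fitted apart from the genes.

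The choices in this paragraph were made before the data were examined. The NCI-H2009 comparison was a limma fit of the 6 arrays without a block. The MYC comparisons came from a single limma fit of the 12 arrays at 12, 24 and 48 h, with cell line by hour as terms and a MYC-minus-control difference for each line, so that the hours served as repeats and no condition was replicated. The difference between the line effects was tested as a contrast of that fit. The 0 h arrays stayed out of it, and their difference is given beside the later one and was subtracted in an alternative. A further fit of the 8 control arrays compared 12, 24 and 48 h with 0 h within line. Moderated statistics were Benjamini-Hochberg adjusted over all genes of a fit, with a threshold of 0.05, two-sided.

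Gene lists, 25 in number, were the MYC network, canonical MYC targets, ribosome biogenesis, RNA polymerases I and III, nucleotide synthesis, cytosolic ribosomal proteins, mitochondrial ribosomal proteins, glycolysis, one-carbon and serine metabolism, G1/S and E2F targets, G2/M, p53 targets, growth arrest and MYC-repressed genes, interferon response, ATF4 and the unfolded protein response, apoptosis regulators, cholesterol synthesis, epithelial, mesenchymal and matrix, neuroendocrine, leukocyte, alveolar and club cell markers, NF-kB inflammatory genes, miR-342-3p targets named in earlier studies, and microRNA machinery. Several share members, so that their tests are not independent. They were tested with limma's camera at an inter-gene correlation of 0.01, adjusted over the 25 lists of a comparison, and again with the correlation estimated for each list. The estimated form rests on the few residual degrees of freedom of a fit, so it has little power here. Many estimates lay far above 0.01, such as 0.51 for G2/M genes in NCI-H2009 and 0.90 for cytosolic ribosomal proteins in the MYC fit. Others did not, such as that of the MYC network in NCI-H2009 (-0.02). Where the members of a list correlate above 0.01, its p-value at 0.01 is too small. For single hours a list's median difference was ranked among 10000 random lists matched on brightness in 20 bins. Genes called with MYC in each line were tested the same way in the NCI-H2009 fit, with which they share no array. The overlap of calls between the MYC lines was tested by Fisher's exact test.

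Named genes followed a rule. They were MYC, E2F1 and EVL, the host gene of miR-342, in every comparison. In each main comparison they were the 10 highest and 10 lowest fold changes past the threshold with a symbol. For miR-342-3p the samples of both arms had to be fully separated, and for MYC each later hour had to lie beyond the 0 h difference in the same direction. They also included up to 4 members of largest change per list, and all members of the MYC network and earlier-target lists. Some members that the rule names are not reported here. For the line difference and the control arrays the 5 highest and 5 lowest are given. Genes named outside the rule were chosen after their values were seen: those passing with the replicate block alone, 5 genes of the NCI-H2009 comparison followed in the MYC lines, and genes behind counts of 4 or fewer.

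The numbers of the NCI-H2009 samples pair the arms. Deviations from the arm mean correlated across genes at r = 0.753, 0.750 and 0.890 within numbers 1, 2 and 3, against 0.560 and 0.495 between different numbers on the same slide and -0.731 to -0.778 across slides. The pairing comes from the shared number and, in part, from the slide. Values with the replicate number as a block (the replicate block) are given where they change a call.

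The alternatives fixed before the data were examined were no background subtraction, the scanner software's ratio, median centring in place of loess, the Cy5 channel alone after quantile normalization, no filter, a filter on every array, the mean over a gene's probes, the series matrix values, array weights, leaving out each sample or hour, a replicate or slide block in NCI-H2009, subtraction of the 0 h difference, each MYC line fitted alone, all 16 MYC arrays in a single fit for the control arrays, other settings and sources for the list tests, and a threshold of 0.1 for the overlap. Slide could be a block in NCI-H2009 alone, since each MYC slide holds a single line. Added after seeing the data were slide 1 alone, list tests with the replicate block, the replicate block together with the Cy5 channel, with the scanner software's ratio and with the strict filter, and a list of BEAS-2B genes called after subtraction of the 0 h difference. Also added then were the line difference lists with both that subtraction and an estimated correlation.

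The fits were tested on simulated data with known changes in a small share of the genes. Noise was drawn independently for each gene and array, with the spread that the fit gave the gene. The simulation thus held no correlation between genes, no pairing beyond the fitted terms and no change of an effect with hour. Its shares can differ from those of the real data, where these are present and many more genes were called. At a log2 change of 0.5, 1 and 2, the share recovered was 1.16%, 62.7% and 93.6% in the NCI-H2009 fit and 91.2%, 100% and 100% with the replicate block. It was 95%, 100% and 100% in BEAS-2B, 96.9%, 100% and 100% in SK-LC-3, 53.0%, 98.6% and 100% for the line difference, 6.90%, 91.7% and 100% in SK-LC-3 minus the 0 h difference, and 88%, 100% and 100% in the control arrays. False calls, in the same order, were 5 of 92, 13 of 207, 19 of 216, 10 of 208, 15 of 183, 6 of 146 and 6 of 197.

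The planned test of genes with a miR-342-3p site in the 3' UTR was not run, because the reference at hand gives gene names and holds no UTR sequence; words in the probe sequences were tested in its place. No group held 4 to 10 samples of the same condition, so no test for outlying samples applied. The number of arrays limits the precision: the median standard error was 0.153 on the log2 scale for miR-342-3p, 0.0843 for each MYC line and 0.119 for the line difference. Nothing in the labels says that the numbered samples were separate cultures, so p-values measure the spread between these samples and no more.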

Results

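Transcript levels were measured on 22 arrays of human lung cell lines, to relate the microRNA miR-342-3p to the transcriptional activity of MYC. BEAS-2B, an immortalized bronchial epithelial line, and SK-LC-3, a lung cancer line, carried either a control construct (Ctrl) or a doxycycline-driven MYC construct, and each was sampled at 0, 12, 24 and 48 h on 1 array. NCI-H2009, a lung adenocarcinoma line, received miR-342-3p or a negative control RNA (NC), with 3 samples each. Between 60.8% and 76.3% of the 58717 spots were well above background in the sample channel, and no spot was saturated. Values are log2 ratios of sample to reference, and differences between arms are log2 fold changes with their standard error (SE). On each MYC slide the reference channel correlated across probes with that line's own 0 h Ctrl sample at r of 0.995 or more and with the reference of the NCI-H2009 slides at 0.933 or less, so ratios are compared within a slide.

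The comparison of miR-342-3p with NC in NCI-H2009 asked which transcripts change when the microRNA is raised. AXL, a receptor tyrosine kinase, was 6.24-fold higher with miR-342-3p (log2 2.64, SE 0.15, n = 3 per arm, limma adjusted p = 0.0156), by 2.50 on slide 1 and 2.92 on slide 2. The transcript of SEC61G, a subunit of the channel through which proteins enter the endoplasmic reticulum, fell by 2.08 (4.23-fold lower, SE 0.19, limma adjusted p = 0.0453), with -1.98 and -2.28 on the slides. INSIG1, which holds the sterol-sensing complex in the endoplasmic reticulum, fell by 1.67 (3.17-fold lower, SE 0.14), with -1.55 and -1.89 on the slides. In hg19 the probes lie at 41767395 to 41767454 on chromosome 19 for AXL, 54820105 to 54823522 on chromosome 7 for SEC61G and 155101843 to 155101902 on chromosome 7 for INSIG1.

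Other genes that rose with miR-342-3p were SPNS2, a sphingosine-1-phosphate exporter (2.93-fold, SE 0.17 on the log2 scale), CHPF, an enzyme of chondroitin synthesis (2.89-fold, SE 0.19), NID1, a basement membrane protein (2.89-fold, SE 0.17), and RILPL2 (2.80-fold, SE 0.18). PYCARD, the adaptor of inflammasomes, rose 2.51-fold, PARP8 2.34-fold, the keratin gene KRT80 2.31-fold, CPNE1 2.30-fold and the transcription factor gene FOXE1 2.30-fold, with FOXE1 well above background on 2 of the 3 NC arrays. Among genes that fell, SLC16A1, a lactate transporter, was 2.80-fold lower, the ubiquitin-conjugating enzyme gene UBE2D2 2.62-fold lower and BBS2, part of a ciliary transport complex, 2.44-fold lower. SCCPDH was 2.84-fold lower, ABHD14A 2.66-fold, PLEKHB2 2.55-fold and the pseudogene GXYLT1P3 2.46-fold. PABIR2 was 3.06-fold lower by its brightest probe (-1.61), while its other probes gave -0.18 and -0.19. All of these had an adjusted p of 0.0453.

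**Figure D1:**
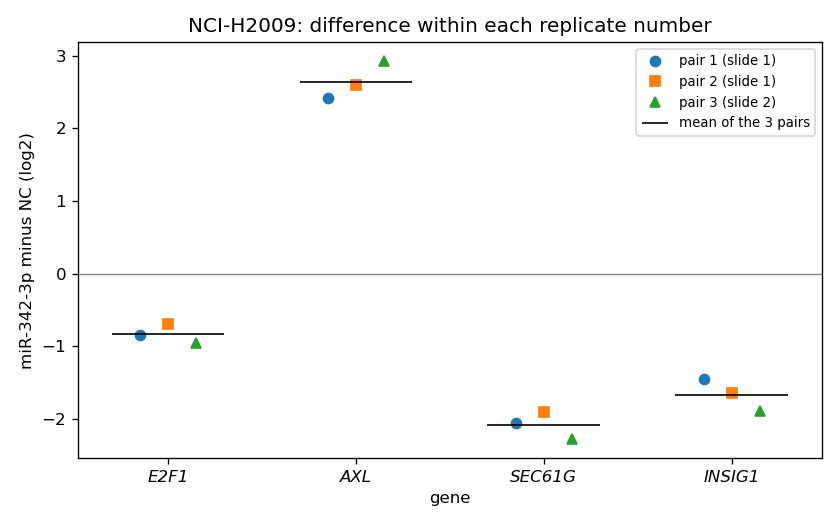
Log2 difference between the miR-342-3p and NC samples of the same number in NCI-H2009 for E2F1, AXL, SEC61G and INSIG1, with a point per pair. AXL lay above 0 and the other genes below 0 in all 3 pairs.

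In all, 52 of 19493 genes passed, 25 higher and 27 lower, 35 of them changed at least 2-fold, and 2292 genes had an unadjusted p under 0.05. With the replicate block the count was 4122, 2222 higher and 1900 lower, which held all of the 52. The samples of the arms were fully separated for 3463 genes, 17.8% of those tested, against 10% by chance if all 6 arrays could be exchanged. Differences between the replicates make the chance share smaller than that. The count rested on each sample: it was 0 without any single array but the third NC array, 2 (AXL and SPNS2) without that one, and with the scanner software's ratio or the series matrix it was 0, with 2069 and 2065 genes at an unadjusted p under 0.05.

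Among the largest changes that passed with the replicate block alone were the chemokine genes CXCL1 (log2 2.64, block adjusted p = 0.00343) and CXCL2 (log2 1.84, block adjusted p = 0.00265), and ASB10 (1.66), CAVIN2 (1.63), CLDN11 (1.55) and P4HA2 (-1.57). E2F1, a transcription factor of the G1/S transition, averaged -1.44 ± 0.12 (SD, n = 3) with miR-342-3p and -0.61 ± 0.04 (SD, n = 3) with NC. The difference of -0.83 (1.78-fold lower, SE 0.11) missed the threshold at a limma adjusted p of 0.0539 and passed with the block at 0.000935 (0.000253 to 0.306 over all alternatives), with -0.77 on slide 1 and -0.95 on slide 2. MYC itself stood at 0.07 (adjusted p = 0.945, block 0.508), and EVL, the host gene of miR-342, at -0.27 (adjusted p = 0.935, block 0.0467).

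Of 14 genes named as miR-342-3p targets in earlier studies, E2F1 and EVL among them, none passed over all genes and E2F1 alone was lower adjusted over the list alone (list adjusted p = 0.636). ID4 stood at -0.58, FOXM1 at 0.30, TAB3 at 0.25, CCND1 at -0.14, AGR2 at -0.13, RAP2B at -0.13, DNMT1 at 0.09, FOXQ1 at -0.07, BMP7 at 0.04, GEMIN4 at 0.04, TAB2 at 0.04 and IKBKG at 0.02. With the block, FOXM1 was higher (adjusted p = 0.0214) and ID4 lower (adjusted p = 0.0281), beside E2F1 and EVL. In the MYC network no member passed over all genes or over the list alone (list adjusted p = 0.738). MAX, the partner of MYC, stood at -0.14, MGA at 0.02, MLX at 0.07, MLXIP at -0.04, MLXIPL at 0.02, MNT at -0.13, MXD1 at 0.06, MXD3 at -0.25, MXI1 at 0.08 and MYCL at 0.26. Block adjusted p-values passed for MIR17HG, the precursor of a microRNA cluster (-0.46), RUVBL1 (-0.45), RUVBL2 (-0.28), MXD4 (0.41) and ZBTB17 (0.28).

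Genes of G2 and mitosis were lower as a group with miR-342-3p. Their median was -0.36 (-0.43 on slide 1, -0.22 on slide 2), and the list test gave an adjusted p of 5.43e-16, with adjusted p = 0.659 with an estimated correlation. None of the 60 passed singly over all genes, 14 were lower adjusted over the list alone, and with the block 42 were lower and 1 higher, among them ANLN (-0.97), BIRC5 (-0.87), AURKB (-0.83) and BUB1 (-0.75). The sterol synthesis list had a median of -0.15 (adjusted p = 5.29e-05, and adjusted p = 0.419 with an estimated correlation). INSIG1 passed among its 24 members, 7 were lower and 1 higher adjusted over the list alone, and with the block 11 were lower and 2 higher, such as IDI1 (-0.74), MSMO1 (-0.62) and HMGCS1 (-0.58).

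Interferon-responsive genes were higher as a group, with a median of 0.38 (0.39 on slide 1, 0.46 on slide 2) and an adjusted p of 1.30e-06, or adjusted p = 0.80 with an estimated correlation. None of the 36 passed singly or adjusted over the list alone, and 23 were higher and 0 lower with the block, such as IFI44L (1.16), IFIT2 (0.96), MX1 (0.95) and OASL (0.91). NF-kB inflammatory genes had a median of 0.35 (0.33 on slide 1, 0.15 on slide 2) and an adjusted p of 0.000822, or adjusted p = 0.659 with an estimated correlation. None of the 24 passed over all genes, 4 were higher adjusted over the list alone, and 9 were higher and 1 lower with the block, including ICAM1, an adhesion receptor (1.05), and the cytokine gene IL6 (0.92). Cytosolic ribosomal protein genes had a median of 0.17 (adjusted p = 4.84e-05, and adjusted p = 0.659 with an estimated correlation), and RPS25 alone of 67 passed (2.11-fold higher), also adjusted over the list alone, with 14 higher and 0 lower in the block.

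Canonical MYC targets had a median of -0.09 in NCI-H2009 (adjusted p = 0.00133, and adjusted p = 0.659 with an estimated correlation). None of the 50 passed over all genes or adjusted over the list alone, and with the block 12 were lower, such as PTMA (-0.61), CDK4 (-0.60) and FBL (-0.53), and 1 was higher. Ribosome biogenesis had a median of -0.10 (adjusted p = 0.00361, and adjusted p = 0.80 with an estimated correlation), with 0 of 71 passing, 1 lower adjusted over the list alone, and 8 lower and 2 higher with the block, such as NHP2 (-0.81). The ATF4 and unfolded protein list had a median of -0.14 (adjusted p = 0.0131, and adjusted p = 0.80 with an estimated correlation). CRELD2, an endoplasmic reticulum stress gene, passed among its 36 members (2.35-fold lower), 2 were lower adjusted over the list alone, and with the block 10 were lower and 2 higher, including the chaperone gene HSPA5 (-0.61).

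G1/S and E2F target genes went both ways. Their median was 0.10 (adjusted p = 0.0261, 0.0565 with the block, and adjusted p = 0.80 with an estimated correlation), none of the 70 passed over all genes, 2 were higher and 2 lower adjusted over the list alone, and with the block 15 were higher, such as UHRF1 (0.76) and TK1 (0.66), and 6 lower, such as RRM2 (-0.97). The other lists did not pass, with adjusted p-values from 0.149 to 0.837: RNA polymerases I and III, nucleotide synthesis, mitochondrial ribosomal proteins, glycolysis, one-carbon and serine metabolism, p53 targets, growth arrest, apoptosis regulators, microRNA machinery, and the epithelial, mesenchymal, neuroendocrine, leukocyte and alveolar markers.

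The MYC construct was compared with the control construct at 12, 24 and 48 h in BEAS-2B, to find what MYC changes in a bronchial epithelial line. Genes of ribosome production rose together: 68 of 71 ribosome biogenesis genes were higher and 0 lower (70 higher adjusted over the list alone), with a median log2 difference of 1.01 against 0.06 at 0 h. After subtraction of the 0 h difference 54 were higher and 0 lower. As a list they lost the call with an estimated correlation (camera adjusted p = 0.166). BOP1 stood at 2.18, NOP16 at 1.99 and WDR43 at 1.73. The largest single rise was that of SLC7A2, a transporter of cationic amino acids, 12.1-fold (log2 3.60, SE 0.13, 1.24 at 0 h, n = 3 hours). MYBBP1A, a nucleolar protein, rose 5.60-fold (SE 0.08), and the matrix and secreted protein genes LGALS1, CCDC80 and SRGN fell 4.37-, 4.17- and 4.14-fold.

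Other genes that rose in BEAS-2B were RNF125, a ubiquitin ligase gene (6.32-fold), NKAIN1 (6.18-fold), the fatty acid binding protein gene FABP5 (5.76-fold), PLD6 (5.64-fold), PPARGC1B, a coactivator of mitochondrial genes (5.55-fold), the non-coding SNHG8 (5.44-fold) and PCOLCE2 (5.28-fold). RPRML rose 5.70-fold by its brightest probe, while its other probe gave 0.32 on the log2 scale. Genes that fell were the non-coding MIR503HG (5.24-fold lower), C1S, a complement protease (4.50-fold, with -0.48 at its other probe), NTN4, a laminin-related protein (4.22-fold), DKK1, a secreted WNT inhibitor (4.05-fold), TM4SF1 (3.76-fold) and CPA4 (3.75-fold). Each had an adjusted p of 3.68e-06 or lower, and after subtraction of the 0 h difference C1S (adjusted p = 0.0784), DKK1 (0.109) and CPA4 (0.179) no longer passed.

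The MYC probe itself read 4.09-fold lower in the MYC arm of BEAS-2B (-2.03, SE 0.09, -0.76 at 0 h) and 3.68-fold lower in that of SK-LC-3 (-1.88, SE 0.09, -1.29 at 0 h). This probe lies at 128753268 to 128753327 on chromosome 8 in hg19, and whether the construct's transcript contains its sequence is unknown, so the probe was not used as a measure of the construct. E2F1 stood at -0.10 in BEAS-2B (adjusted p = 0.489) and -0.01 in SK-LC-3 (adjusted p = 0.933). EVL was higher by 0.43 in BEAS-2B (SE 0.07, adjusted p = 0.000736; 0.16 at 0 h) and by 0.76 in SK-LC-3 (1.69-fold, SE 0.07, adjusted p = 1.67e-05; 1.05 at 0 h). With the 0 h difference subtracted it passed in neither line, at 0.27 (adjusted p = 0.310) and -0.30 (adjusted p = 0.493).

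**Figure D2:**
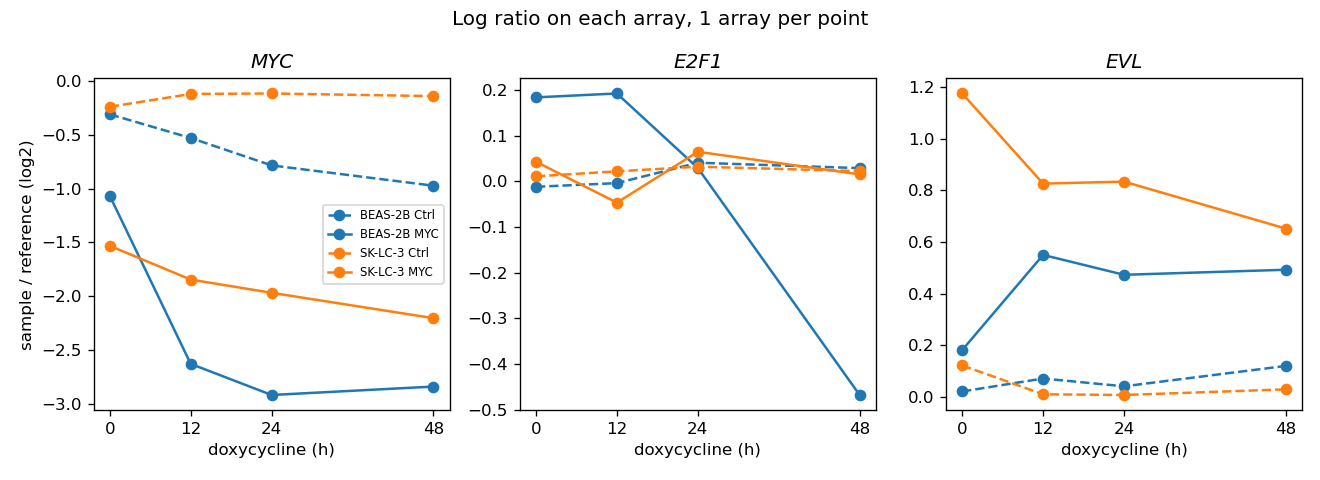
Log2 ratio of sample to reference for MYC, E2F1 and EVL by hours of doxycycline, with a point per array of each line and construct. The MYC probe lay lower in the MYC arm than in the Ctrl arm at every hour in both lines.

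Canonical MYC targets rose in BEAS-2B, 45 of 49 higher and 1 lower with a median of 1.07 (0.09 at 0 h; adjusted p = 1.13e-25, and adjusted p = 0.166 with an estimated correlation). The polyamine enzyme gene SRM stood at 1.73 among them. The ribosome biogenesis list had an adjusted p of 5.59e-34, and adjusted p = 0.166 with an estimated correlation. Among subunits and factors of RNA polymerases I and III, 27 of 34 rose and 1 fell (median 0.52, adjusted p = 5.85e-11, and adjusted p = 0.166 with an estimated correlation), such as POLR1B (1.76), POLR3E (1.57) and POLR1G (1.30). Nucleotide synthesis genes had 18 of 25 higher and 5 lower (median 0.58, adjusted p = 4.16e-06, and adjusted p = 0.256 with an estimated correlation), with DHODH (1.44) and PPAT (1.31).

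Cytosolic ribosomal protein genes in BEAS-2B had 55 of 67 higher and 0 lower (median 0.37, adjusted p = 1.55e-12, and adjusted p = 0.427 with an estimated correlation), such as RPL27A (0.79), and none passed singly after subtraction of the 0 h difference. Mitochondrial ribosomal protein genes had 45 of 62 higher and 3 lower (median 0.42, adjusted p = 1.12e-11, and adjusted p = 0.256 with an estimated correlation), with MRPL3 at 1.17. After subtraction 11 of these were higher over all genes, as were 39 of the canonical MYC targets, 12 of the RNA polymerase genes and 12 of the nucleotide synthesis genes. One-carbon and serine genes had 6 of 13 higher and 1 lower (median 0.25, adjusted p = 0.0308, and adjusted p = 0.313 with an estimated correlation), led by the folate carrier gene SLC19A1 (1.45), and the list missed the threshold after subtraction of the 0 h difference (adjusted p = 0.0573).

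Lower in BEAS-2B were 52 of 60 G2/M genes with 0 higher (median -0.53, adjusted p = 7.84e-14, and adjusted p = 0.256 with an estimated correlation), such as ANLN (-1.15), and 9 after subtraction of the 0 h difference. Of the growth arrest and MYC-repressed genes 23 of 28 fell and 2 rose (median -0.74, adjusted p = 3.50e-09, and adjusted p = 0.166 with an estimated correlation), including the cell cycle inhibitor genes CDKN1C (-1.71) and CDKN2C (-1.35) and CAV1 (-1.49), and 12 were lower after subtraction. In the mesenchymal and matrix list 25 of 29 fell and 2 rose (median -0.86, -0.40 at 0 h; adjusted p = 1.37e-10, and adjusted p = 0.166 with an estimated correlation), with SPARC (-1.67), TGFBI (-1.62, -1.16 at 0 h) and COL1A1 (-1.61). After subtraction of the 0 h difference 5 were lower and 0 higher, and SPARC (adjusted p = 0.0932), TGFBI (0.245) and COL1A1 (0.0522) no longer passed. Sterol synthesis had 22 of 24 lower and 0 higher (median -0.67, -0.39 at 0 h; adjusted p = 3.33e-10, and adjusted p = 0.256 with an estimated correlation), with INSIG1 (-1.75, -0.88 at 0 h) and HMGCS1 (-1.23, -0.82 at 0 h). After subtraction 2 of the 24 were lower, and HMGCS1 no longer passed (-0.42, adjusted p = 0.329).

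Interferon-responsive genes in BEAS-2B had 28 of 38 lower and 1 higher (median -0.56, -0.14 at 0 h; adjusted p = 1.31e-07, and adjusted p = 0.313 with an estimated correlation), with IFIT3 (-1.48), IFIT1 (-1.38) and STAT2 (-1.23). After subtraction of the 0 h difference 6 of these were lower, STAT2 among them, and IFIT3 (adjusted p = 0.0570) and IFIT1 (0.165) no longer passed. Of p53 targets 14 of 31 fell and 5 rose (median -0.19, adjusted p = 0.0308, and adjusted p = 0.427 with an estimated correlation); TP53INP1 stood at -1.27, CDKN1A at -0.92 and AEN at 0.99, and after subtraction 4 were lower and 1 higher. NF-kB inflammatory genes had 11 of 25 lower and 2 higher (median -0.33, adjusted p = 0.00326, and adjusted p = 0.389 with an estimated correlation). Of their 4 largest members CCL2 stood at -2.60 later and -2.69 at 0 h, CXCL1 at -1.74 and -3.23, TNFAIP2 at -1.44 and -0.73, and IL6 at -1.17 and -1.18. After subtraction of the 0 h difference this list turned to higher (adjusted p = 0.680).

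The other lists did not pass in BEAS-2B. In the MYC network 8 of 16 members rose and 3 fell (adjusted p = 0.0983): MIR17HG (1.43), MXI1 (1.06), RUVBL1 (0.98), MNT (0.73), MAX (0.66), RUVBL2 (0.56), MGA (0.52) and MLXIP (0.40) were higher, and MYC, MXD3 (-0.88) and MXD1 (-0.41) lower, while MXD4 (-0.25), MLX (0.13), MYCL (-0.05), ZBTB17 (-0.04) and MLXIPL (-0.02) did not pass. Glycolysis had 6 genes higher, with HK2 (1.28) and PDK1 (1.06), and 11 lower, with ALDOC (-1.17). G1/S and E2F targets had 8 of 70 higher, with CDCA7 (1.36), and 20 lower, with TK1 (-1.42). ATF4 and unfolded protein genes had 4 higher and 12 lower, apoptosis regulators 5 and 14, epithelial genes 5 and 9, alveolar markers 2 and 1, leukocyte markers 0 and 3, and microRNA machinery 4 and 1, with XPO5 at 1.22. The neuroendocrine marker DLL3 stood at 1.08. Of the earlier miR-342-3p targets 3 rose, GEMIN4 (0.67) and EVL among them, and 5 fell, including FOXM1 (-0.58) and TAB2 (-0.43).

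Subtraction of the 0 h difference left fewer of these calls in BEAS-2B. The MYC network then had 4 higher and 2 lower, without MNT (adjusted p = 0.0623), RUVBL2 (0.0774), MGA (0.0515), MLXIP (0.665) and MXD1 (0.444). Glycolysis had 5 higher and 0 lower, without ALDOC (adjusted p = 0.0866), ATF4 and unfolded protein genes 0 and 0, apoptosis regulators 2 and 1, epithelial genes 1 and 2, alveolar and leukocyte markers 0 and 0, microRNA machinery 1 and 0, and the earlier miR-342-3p targets 2 and 0. G1/S and E2F targets had 2 higher and 6 lower, and as a list they then passed as lower (median -0.15, adjusted p = 0.00994, and adjusted p = 0.610 with an estimated correlation).

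In BEAS-2B 8377 of 18342 genes passed, 3880 higher and 4497 lower, 754 of them changed at least 2-fold. The count was 5537 without the 24 h arrays and 1501 after subtraction of the 0 h difference (855 higher, 646 lower). The subtraction rests on 1 array per arm at 0 h and raised the SE, for MYBBP1A from 0.08 to 0.17. Part of the drop can thus come from lower precision. Each p rests on the spread of the difference between hours.

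The same comparison in SK-LC-3 asked what MYC changes in a lung cancer line. The transcript of GNG11, a G protein subunit, was 47.5-fold lower with MYC (-5.57, SE 0.11, n = 3 hours), and it stood at -5.44 at 0 h. UBE2C, a mitotic ubiquitin-conjugating enzyme gene, was 14.6-fold lower (-3.87, SE 0.07, -3.66 at 0 h). GALNT16, a glycosyltransferase gene, was 12.1-fold higher (3.59, SE 0.23, 1.1 at 0 h), and RGS16, a regulator of G protein signalling, 7.98-fold higher (3.00, SE 0.20, 0.28 at 0 h), with 1.18 at its other probe. The cytokine gene IL6 was 12.7-fold higher (3.67) and stood at 3.99 at 0 h.

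Genes higher in the MYC arm of SK-LC-3 also included the neuropeptide gene GAL (7.69-fold), the ubiquitin-like gene UBD (7.21-fold, 2.74 at 0 h, well above background on 2 of the 3 Ctrl arrays), CCDC3 (6.47-fold), ICAM1 (5.99-fold, 2.22 at 0 h), SUSD3 (4.76-fold), the fatty acid enzyme gene SLC27A2 (4.51-fold), LAMA1 (4.34-fold, 0.81 at its other probe) and STEAP1 (4.24-fold). Lower were DAW1 (17.5-fold), DNAH17, a dynein heavy chain gene (17.4-fold, 0.03 at its other probe), IGFBP7 (13.2-fold), MLLT11 (12.8-fold), N-cadherin CDH2 (log2 -3.46, -2.12 at its other probe), the collagen crosslinking enzyme gene LOX (10.6-fold) and SNX7 (9.78-fold). TMTC1 was at least 16.2-fold lower, with no signal well above background in the MYC arm, and its other probes gave -3.06 and -0.54. These had adjusted p-values of 5.90e-06 or lower, and none passed after subtraction of the 0 h difference, RGS16 coming nearest at an adjusted p of 0.0759.

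The arms of SK-LC-3 differed before doxycycline. Across genes the 0 h and later differences correlated at r = 0.83, against 0.48 in BEAS-2B, and the SD of the difference across genes was 0.44 at 0 h and 0.44 to 0.46 later, against 0.22 and 0.39 to 0.50 in BEAS-2B (genes are not independent replicates). Of the genes called in SK-LC-3, 4882 (70.8%) had at 0 h at least 50% of the later log2 difference and 6205 (90.0%) had the same sign, against 1842 (22.0%) and 6216 (74.2%) in BEAS-2B. The count in SK-LC-3 was 6897 of 18342 genes, 3270 higher and 3627 lower, 658 of them changed at least 2-fold. It was 4335 without the 24 h arrays, and 0 by limma after subtraction of the 0 h difference, with 2025 genes at an unadjusted p under 0.05. The subtraction also raised the SE, for RGS16 from 0.20 to 0.39, with 2.72 left of its difference of 3.00. Lower precision and the 0 h difference thus both enter the drop.

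**Figure D3:**
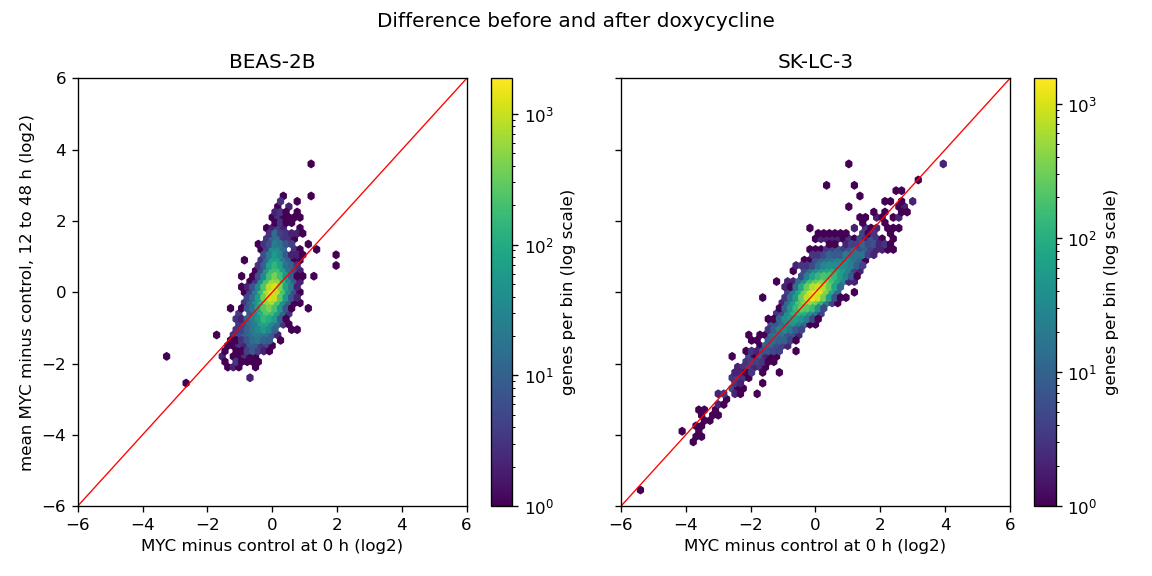
MYC-minus-control log2 difference at 0 h against that over 12 to 48 h, binned over all genes tested, in BEAS-2B and SK-LC-3. The correlation across genes was 0.48 in BEAS-2B and 0.83 in SK-LC-3.

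NF-kB inflammatory genes were higher in the MYC arm of SK-LC-3, 24 of 25 with 0 lower (median 1.13, adjusted p = 2.80e-17, and adjusted p = 0.217 with an estimated correlation), including BIRC3 (2.49) and CXCL1 (2.36), and stood at 1.26 at 0 h. Interferon-responsive genes had 25 of 38 higher and 1 lower (median 0.52, 0.58 at 0 h; adjusted p = 6.39e-09, and adjusted p = 0.567 with an estimated correlation), such as IFI27 (2.62), IFI6 (2.36) and ISG15 (2.09). Of p53 targets 25 of 31 were higher and 2 lower (median 0.45, 0.42 at 0 h; adjusted p = 8.20e-09, and adjusted p = 0.292 with an estimated correlation), such as BTG2 (1.43) and GADD45A (1.15). With the 0 h difference subtracted the interferon list was lower (median -0.15, adjusted p = 0.0181, and adjusted p = 0.581 with an estimated correlation), NF-kB genes did not pass (median -0.18, adjusted p = 0.101), and 15 of 31 p53 targets had values above 0 (adjusted p = 0.894).

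Ribosome biogenesis genes moved the other way over time in SK-LC-3, from a median of -0.17 at 0 h to 0.24 later (36 of 71 higher, 1 lower, adjusted p = 3.76e-08, and adjusted p = 0.694 with an estimated correlation), such as NOL6 (0.64), RRP1B (0.62) and WDR74 (0.61). Canonical MYC targets went from -0.20 at 0 h to 0.08 at 12 h, 0.20 at 24 h and 0.31 at 48 h. Over the later hours 22 of 49 were higher and 4 lower (median 0.25, adjusted p = 8.62e-05, and adjusted p = 0.700 with an estimated correlation). Among the higher were the telomerase gene TERT (1.73), the transferrin receptor gene TFRC (0.85) and PRMT5 (0.69). List p-values after subtraction rest on 1 array per arm at 0 h and do not measure the spread between arrays of that hour. After subtraction of the 0 h difference both medians were 0.41, with adjusted p-values of 2.83e-27 for ribosome biogenesis and 8.76e-19 for MYC targets, each with adjusted p = 0.286 with an estimated correlation, and 29 and 18 members were higher adjusted over the list alone although 0 passed over all genes.

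Lower in SK-LC-3 were 23 of 26 epithelial genes with 1 higher (median -0.74, -0.53 at 0 h; adjusted p = 1.25e-10, and adjusted p = 0.214 with an estimated correlation), including KRT19 (-1.38), EPCAM (-1.28) and RAB25 (-1.19), and after subtraction of the 0 h difference the list median was -0.19 (adjusted p = 0.0129, and adjusted p = 0.324 with an estimated correlation). G2/M genes had 46 of 60 lower and 1 higher (median -0.43, also -0.43 at 0 h; adjusted p = 3.52e-11, and adjusted p = 0.523 with an estimated correlation), such as ANLN (-0.86) and SPC25 (-0.82). G1/S and E2F targets had 34 of 70 lower and 5 higher (median -0.21, -0.39 at 0 h; adjusted p = 0.000351, and adjusted p = 0.700 with an estimated correlation), such as RPA3 (-1.12) and GMNN (-0.96). Sterol synthesis had 12 of 24 lower and 0 higher (median -0.21, adjusted p = 0.0222, and adjusted p = 0.700 with an estimated correlation). With the 0 h difference subtracted, G2/M genes had 30 of 60 values above 0 (adjusted p = 0.728) and sterol synthesis 14 of 24 (adjusted p = 0.704), and G1/S and E2F targets turned to higher (adjusted p = 1.64e-06, and adjusted p = 0.506 with an estimated correlation).

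The other lists did not pass in SK-LC-3, and several held large changes in both directions. Mesenchymal and matrix genes had 7 of 29 higher and 11 lower, among them CDH2, LOX, COL5A1 (-2.65) and vimentin VIM (-1.57). Growth arrest genes had 7 higher and 8 lower, with NDRG1 (-2.25) and CDKN2C (-1.43), apoptosis regulators 11 and 6, with PMAIP1 (1.23), RNA polymerases I and III 11 and 3, with POLR3G (1.46), nucleotide synthesis 7 and 5, and cytosolic ribosomal proteins 6 and 16, with RPS18 (-1.12, -1.18 at 0 h). Mitochondrial ribosomal proteins had 10 higher and 7 lower, glycolysis 5 and 6, one-carbon and serine 5 and 2, with PHGDH (1.14), ATF4 and unfolded protein genes 5 and 6, alveolar markers 4 and 1, and microRNA machinery 3 and 3. The leukocyte markers CD14 (1.75) and ITGB2 (1.20) were among 4 of 12 higher and 2 lower, and the neuroendocrine marker SCG2 stood at -1.88. Earlier miR-342-3p targets had 4 higher, with EVL, and 5 lower, with ID4 (-1.50), FOXQ1 (-0.92) and AGR2 (-0.83).

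With the 0 h difference subtracted, 11 of these other lists passed in SK-LC-3. All of them share 1 array per arm at 0 h, so these calls do not measure the spread between arrays of that hour. Higher were nucleotide synthesis (adjusted p = 9.42e-08), RNA polymerases I and III (6.02e-07), mitochondrial ribosomal proteins (0.000337), cytosolic ribosomal proteins (0.000543), one-carbon and serine (0.00230) and the MYC network (0.0375). Lower were leukocyte markers (0.00869), glycolysis (0.0203), mesenchymal and matrix genes (0.0234), ATF4 and unfolded protein genes (0.0326) and growth arrest genes (0.0328). None passed with an estimated correlation, from adjusted p = 0.286 with an estimated correlation to 0.670.

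In the MYC network 6 of 16 members were higher in the MYC arm of SK-LC-3, MYCL (0.99), MLXIPL (0.35), MAX (0.34), MLX (0.32), MGA (0.29) and RUVBL2 (0.27), and 4 lower, MYC, MXD3 (-0.51), MIR17HG (-0.27) and MXD1 (-0.25). RUVBL1 (0.25), MXD4 (-0.15), MNT (-0.14), MXI1 (-0.09), ZBTB17 (0.04) and MLXIP (0.02) did not pass, nor did the list (adjusted p = 0.622).

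**Figure D4:**
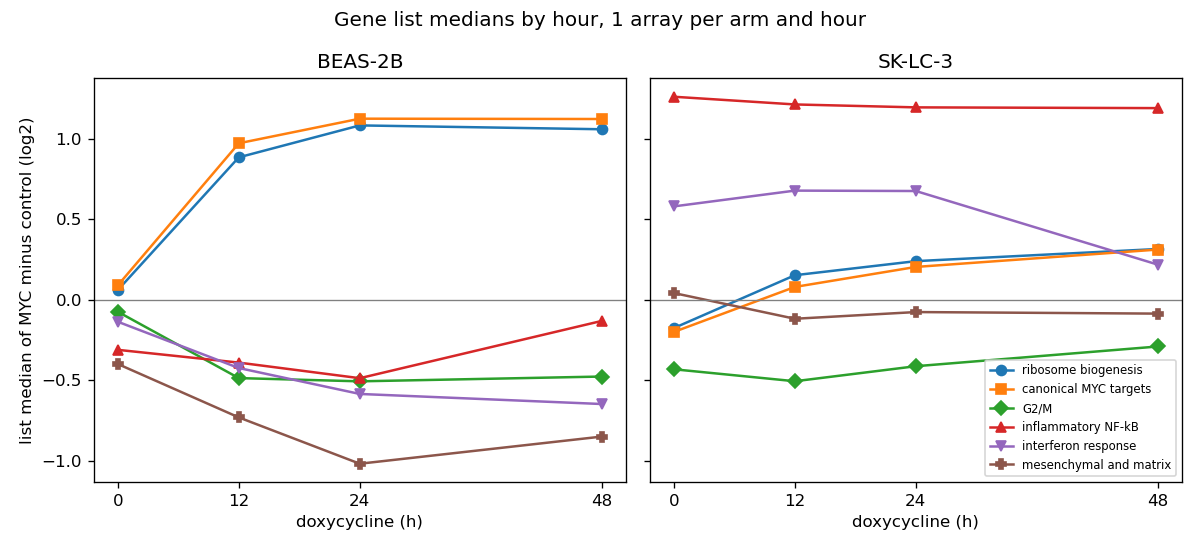
Median MYC-minus-control log2 difference of 6 gene lists at 0, 12, 24 and 48 h of doxycycline in BEAS-2B and SK-LC-3. Canonical MYC targets went from 0.09 at 0 h to 0.97 at 12 h in BEAS-2B and from -0.20 to 0.08 in SK-LC-3.

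The differences between the MYC and control arms were then set against each other, as that in SK-LC-3 minus that in BEAS-2B. IL6 differed most, by 4.83 (-1.17 in BEAS-2B and 3.67 in SK-LC-3), followed by CCL2 (4.25), CXCL1 (4.10), GALNT16 (3.90) and the complement gene CFB (3.74; -1.39 and 2.35). On the other side were TRABD2A (-4.70; 1.40 and -3.30), GNG11 (-4.30), DNAH17 (-4.20), DAW1 (-3.90) and TMTC1. For TMTC1, CCL2, CXCL1 and DNAH17 an arm of a line had no signal well above background, so these differences and their order are not exact. The difference passed for 7679 of 18342 genes, 3737 higher and 3942 lower in SK-LC-3, and the count was 4541 without the 24 h arrays and 4 after subtraction of the 0 h differences (HES7, PCOLCE2, TNFRSF21 and TRIML2). Of the named genes IL6, CCL2, CXCL1, GNG11, DNAH17 and DAW1 then changed sign.

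Of the 25 lists, 14 differed between the lines, and all lost the call with an estimated correlation (lowest adjusted p = 0.211). Of these, 5 no longer passed after subtraction of the 0 h differences: cytosolic ribosomal proteins (adjusted p = 0.163), apoptosis regulators (0.115), epithelial genes (0.908), mesenchymal and matrix genes (0.0663) and NF-kB inflammatory genes, whose direction then was lower (0.138). G1/S and E2F targets (adjusted p = 1.68e-09, higher in SK-LC-3), G2/M genes (2.00e-13, higher) and glycolysis (0.000718, lower) newly passed, each with adjusted p = 0.508 with an estimated correlation. List p-values after subtraction rest on 1 array per arm and line at 0 h and do not measure the spread between arrays of that hour. Genes higher in the MYC arm of both lines numbered 1073 against 691.7 for independent lists (Fisher's exact test, odds ratio 2.13, p = 6.37e-67). Genes lower in both numbered 1360 against 889.3 (Fisher's exact test, odds ratio 2.21, p = 1.69e-85). Another 1334 were called in opposite directions, a number not set against a count for independent lists. The lines share a fit and a residual spread per gene, so genes of low spread are called more readily in both. The calls of the lines are thus not independent. After subtraction of the 0 h difference 0 genes passed in SK-LC-3, so the overlap is not known to be a shared response to MYC. Across genes the fold changes of the lines correlated at r = 0.15 (Spearman 0.16), and at 0.39 after subtraction of the 0 h differences; genes are not independent replicates, so the p-values of the overlap are nominal.

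Genes called between the MYC and control arms were followed in the NCI-H2009 comparison, to ask whether miR-342-3p moves them. Those of SK-LC-3 are not known to respond to MYC, since 0 passed after subtraction of the 0 h difference. That subtraction also raised the SE, so a response of single genes is not excluded. The 3804 measured genes higher with MYC in BEAS-2B had a median of -0.02 with miR-342-3p (adjusted p = 0.272), and the 4314 lower genes 0.04 (adjusted p = 0.334). The 3119 genes higher in SK-LC-3 had a median of 0.02 and the 3495 lower genes 0.00188, both at an adjusted p of 0.586. None of the 4 lists passed, with or without the block. At a fixed correlation of 0.01 the variance of this test grows with list size, so long lists leave it little power. The lack of a pass thus does not show that these genes stayed unchanged. With the block, single genes called higher and lower numbered 358 and 521 among the BEAS-2B higher genes, and 830 and 547 among the lower. Among the SK-LC-3 higher genes they numbered 504 and 369, and among the lower 514 and 508. With shorter lists of about 100 genes of largest moderated t, the 98 highest BEAS-2B genes passed at a median of -0.07 (adjusted p = 0.00235) and the 89 highest SK-LC-3 genes at 0.17 (adjusted p = 0.00139), in opposite directions. The 845 genes higher in BEAS-2B after subtraction of the 0 h difference passed at -0.06 (camera adjusted p = 0.00753). The 615 lower genes did not (0.04, adjusted p = 0.340). The estimated correlation was not applied to any of these shorter lists.

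Control cells at 12, 24 and 48 h were compared with 0 h, which measures doxycycline and time in culture together without the MYC construct. No gene of 18326 passed in limma, and 1127 had an unadjusted p under 0.05. By value, and without passing (adjusted p from 0.761 to 0.841), the highest were GALNT16 (0.97), LOXL4 (0.83), EDN2 (0.82), ND6 (0.76) and CENPT (0.71), and the lowest PTX3 (-0.83), CXCL1 (-0.80), IL6 (-0.65), THBS1 (-0.54) and IL7R (-0.52). All of these but ND6 (0.35 in BEAS-2B and 1.16 in SK-LC-3) came mostly from BEAS-2B, such as GALNT16 (1.96 and -0.02), LOXL4 (1.85 and -0.19), CENPT (1.48 and -0.06) and PTX3 (-1.64 and -0.02). MYC stood at -0.17 (adjusted p = 0.847), a mean over lines that moved in opposite directions. In BEAS-2B Ctrl its log ratio was -0.31 at 0 h and -0.53, -0.79 and -0.97 at 12, 24 and 48 h. In SK-LC-3 Ctrl it was -0.24 and then -0.12, -0.12 and -0.14, with 1 array per hour. The fit takes a single change for both lines, so a change in 1 line is averaged and adds to the residual. A lack of calls thus does not show that genes stayed unchanged in each line.

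Of the lists 10 passed in the control cells, with medians of at most 0.10 in size. Lower were ribosome biogenesis (-0.08, adjusted p = 7.70e-07), canonical MYC targets (-0.08, 4.71e-06), G1/S and E2F targets (-0.06, 2.24e-07), nucleotide synthesis (-0.08, 0.00272), NF-kB (-0.08, 0.0228), G2/M (-0.03, 0.0235) and RNA polymerases I and III (-0.05, 0.0412). Higher were interferon response (0.07, 0.00247), sterol synthesis (0.10, 0.00886) and glycolysis (0.08, 0.0264). None passed with an estimated correlation, the lowest adjusted p being 0.706.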

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

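The tests of the slide row, of a mislabelled hour, of MYC before doxycycline and of the reference channel were chosen only after the results were seen. The lists, the test between lines and the regroupings were planned.

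The difference between the MYC and control arms was not the same in SK-LC-3 and BEAS-2B for 7679 genes by a test of the difference itself, and for 4 after subtraction of the 0 h differences. Among the gene lists, the SK-LC-3 value was higher for NF-kB inflammatory genes (median difference 1.27), the interferon response (1.26), mesenchymal and matrix genes (0.78), p53 targets (0.68), growth arrest genes (0.56), sterol synthesis (0.44) and apoptosis regulators (0.29). It was lower for canonical MYC targets (-0.82), ribosome biogenesis (-0.73), nucleotide synthesis (-0.60), epithelial genes (-0.58), RNA polymerases I and III (-0.48), cytosolic ribosomal proteins (-0.47) and mitochondrial ribosomal proteins (-0.32). All 14 of these calls were lost with an estimated correlation, the lowest being adjusted p = 0.211 with an estimated correlation. Once the 0 h differences were subtracted, cytosolic ribosomal proteins, apoptosis regulators, epithelial genes and mesenchymal and matrix genes no longer passed, and NF-kB genes did not pass either, with the direction reversed (adjusted p = 0.138). Of the 168 list members named for a MYC line, 128 differed between the lines, as did 45 of the 47 other genes named. Over all genes it was 7679 of 18342. The named genes were mostly chosen for large changes on these same arrays, some for this very difference, so their higher share is no separate evidence.

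Genes with the higher value in SK-LC-3 were IL6 (4.83), CCL2 (4.25), CXCL1 (4.10), GALNT16 (3.90), CFB (3.74), ICAM1 (3.51), SRGN (3.38), UBD (3.02), C1S (2.91), MIR503HG (2.86), NTN4 (2.81), GAL (2.80), SUSD3 (2.57), CPA4 (2.41), RGS16 (2.12), LGALS1 (1.89), STEAP1 (1.84), CCDC80 (1.77), TM4SF1 (1.75), DKK1 (1.45), CCDC3 (1.36), SLC27A2 (1.20), LAMA1 (0.49) and EVL (0.33). Those with the lower value were TRABD2A (-4.70), GNG11 (-4.30), DNAH17 (-4.20), DAW1 (-3.90), TMTC1 (-3.75, not exact), UBE2C (-3.41), MLLT11 (-3.21), SLC7A2 (-3.12), CDH2 (-2.99), SNHG8 (-2.65), SNX7 (-2.43), LOX (-2.21), MYBBP1A (-2.11), IGFBP7 (-2.07), RPRML (-2.0), FABP5 (-1.75), PPARGC1B (-1.49), PCOLCE2 (-1.38), NKAIN1 (-1.31), PLD6 (-1.27) and RNF125 (-1.19). For TMTC1, CCL2, CXCL1, UBD, STEAP1, GAL, CPA4, DNAH17 and RPRML an arm of a line had no signal well above background, so these differences and their order are not exact.

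Much of the line difference was present in SK-LC-3 at 0 h, where GNG11 stood at -5.44, UBE2C at -3.66 and IL6 at 3.99 before doxycycline. A slide row effect as the whole cause was argued against in SK-LC-3 by the reference channel, whose SD between the rows was 0.294 of the SD of the arm difference at 0 h. In BEAS-2B it was 0.622 at 0 h, so a row effect on the smaller 0 h difference there stays open. A 0 h array that was in fact of a later hour was argued against by canonical MYC targets, at -0.199 at 0 h and 0.08 to 0.31 later. MYC expressed before doxycycline as the sole cause was argued against by the same median, which lay at percentile 0.02 of random lists at 0 h. In BEAS-2B that median was 0.09 at 0 h, at percentile 99.98. MYC before doxycycline thus stays open in BEAS-2B, where the subtracted 0 h difference may hold some of its effect. Arms that were derived or kept apart before the experiment may carry such differences; this stayed open and was not tested, so how much of the later difference is due to MYC in this line is unknown.

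The reference channel of the MYC slides differed from that of the NCI-H2009 slides, although the labels describe a common pool. Its correlation with them reached at most 0.933, against 0.968 between the NCI-H2009 slides, which argues against the same pool throughout. Its correlation with the 0 h Ctrl sample of the same line was at least 0.995, while samples of different lines reached at most 0.895, which is consistent with RNA of the line's own control cells as the reference. The SD of log ratios was 0.15 to 0.49 on the MYC slides and 0.73 to 0.81 on the NCI-H2009 slides. Differences between arms of a slide do not depend on this, and no biological explanation was tested.

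Probes with no gene name, fitted apart from the genes, also differed between the MYC and control arms. In BEAS-2B 558 of 3828 passed (14.6%, 381 higher and 177 lower) and in SK-LC-3 257 passed (6.71%, 97 higher and 160 lower), against 0 of 3826 in limma among the control arrays (205 at an unadjusted p under 0.05) and 0 of 4326 with miR-342-3p (96). After subtraction of the 0 h difference 19 of 3948 passed in BEAS-2B (18 higher and 1 lower) and 0 in SK-LC-3, where the difference is therefore not ascribed to MYC.

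The splits of the samples were too few for a share under 0.05 in every comparison. Among 10 splits of the NCI-H2009 arrays, 1, the real one, gave as many genes as 52, and the highest of the others gave 0. With the replicate block, 1 of 4 splits gave 4122 and the highest of the others 0. For BEAS-2B 1 of 4 gave 8377, for SK-LC-3 1 of 4 gave 6897 and for the line difference 1 of 10 gave 7679, each with 0 as the highest of the others. Regrouping the MYC arrays puts a steady difference between arms or lines into the residual. The counts of 0 would thus follow from any steady difference, including that of SK-LC-3 at 0 h, and do not bear on its cause.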

How the results depend on the processing

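Added after seeing the data were slide 1 alone, list tests with the replicate block, the block together with another setting, the BEAS-2B list after subtraction of 0 h, and the line difference lists with both that subtraction and an estimated correlation. Of 115 alternatives for counts, lists and overlaps, 80 stayed within 1.5 times or on the same side of the threshold, 32 moved further and 3 passed where the reported value did not. Of 1230 values of named genes, 1007 kept their direction and side of the threshold, 204 no longer passed, 12 newly passed and 7 reversed.

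The miR-342-3p count of 52 was 0 with the scanner software's ratio and with the series matrix, 8 with median centring (2 higher, 6 lower), 516 with the Cy5 channel alone, 1555 with array weights, 3042 with a slide block and 4122 with the replicate block. Leaving out an array gave 0 to 2, with fewer arrays in the fit. With slide 1 alone it was 1132, and with the block it was 5370 in the Cy5 channel, 842 with the scanner software's ratio and 4534 with the strict filter. The block ended the call of the G1/S list and changed no other list call. For named genes in NCI-H2009 174 of 481 values no longer passed and none reversed, and E2F1 passed in 9 alternatives. The causes were not tested, except that a slide block and the replicate block remove the difference between slides.

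Without the 24 h arrays the counts were 5537 in BEAS-2B, 4335 in SK-LC-3 and 4541 for the line difference, with fewer arrays in the fit; leaving out another hour gave at most 7582, 5653 and 6467. With the 0 h difference subtracted they were 1501, 0 and 4 (1 higher, 3 lower), with a larger SE. EVL in SK-LC-3 then reversed to -0.30, and in the line difference IL6 (-0.34), CCL2 (-0.19), CXCL1 (-1.69), GNG11 (1.05), DNAH17 (0.31) and DAW1 (0.0499) reversed, since their 0 h difference was as large as the later one or larger. Other alternatives gave 6987 to 8883 genes in BEAS-2B. Median centring moved the share of higher calls from 46.3% to 62.5% in BEAS-2B and from 48.7% to 33.8% in the line difference, whose median over all genes became -0.12. The control arrays gave 1 gene with the Cy5 channel alone (LINC00458, lower) and 1 with all 16 arrays in a single fit (SAP130, higher).

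With an estimated correlation 0 lists passed in any comparison, against 9 for miR-342-3p, 14 in BEAS-2B, 9 in SK-LC-3, 14 for the line difference and 10 in the control arrays. This form has few residual degrees of freedom, so a lost call does not show that a list stayed unchanged. Ribosome biogenesis in BEAS-2B, with 68 of 71 genes higher, had an unadjusted camera p of 0.0296 in it. With the 0 h difference subtracted 16 passed in SK-LC-3, 9 of them higher, and 12 for the line difference, or 0 with an estimated correlation too. The genes called between the MYC and control arms passed in NCI-H2009 in 3 shorter lists: BEAS-2B higher at -0.0743 among the 100 genes of largest moderated t and at -0.0609 among those called after subtraction of 0 h, and SK-LC-3 higher at 0.17. The estimated correlation was not applied to these 3 lists. The test of 3' UTR sites and its alternatives were not run, since no UTR sequence was at hand. Where a replicate left out leaves 2 samples in an arm, the spread is pooled over both arms. Signal over background limits the dim genes, such as TMTC1 and UBD, whose fold depends on the offset.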

Other observations

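The tests of probe words were planned before the data were examined, and the genes and counts of the next paragraph were chosen after the values were seen.

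Some genes that changed with miR-342-3p in NCI-H2009 also differed between the MYC and control arms. Of the 52, 36 passed in BEAS-2B (69.2%) and 26 in SK-LC-3, against 8118 and 6614 of the 17457 genes measured in both (46.5% and 37.9%), and no test of this excess was made. These are calls before subtraction of the 0 h difference, after which 1501 genes passed in BEAS-2B and 0 in SK-LC-3. Others hardly moved, such as UBE2D2 (0.06 in BEAS-2B, 0.07 in SK-LC-3) and ABHD14A (0.10, 0.07). AXL, higher with miR-342-3p (2.64), was lower with MYC in BEAS-2B (-1.33, SE 0.15, -0.44 at 0 h, adjusted p = 3.61e-05) and in SK-LC-3 (-2.85, SE 0.15, -2.45 at 0 h, adjusted p = 1.41e-07). SLC16A1, lower with miR-342-3p (-1.48), was higher with MYC in BEAS-2B (0.72, SE 0.08, adjusted p = 5.16e-05) and in SK-LC-3 (0.29, SE 0.08, adjusted p = 0.0188). SPNS2 was higher with miR-342-3p (1.55), higher with MYC in BEAS-2B (1.32) and lower in SK-LC-3 (-1.07, -1.25 at 0 h). INSIG1 and SEC61G were lower in all 3 comparisons, INSIG1 at -1.67 with miR-342-3p, -1.75 in BEAS-2B and -0.62 in SK-LC-3, and SEC61G at -2.08, -0.35 and -0.91. After subtraction of the 0 h difference SPNS2 (adjusted p = 0.00149), INSIG1 (0.0197) and SLC16A1 (0.0243) still passed in BEAS-2B, and AXL (0.0915) and SEC61G (0.210) did not; none of these 5 passed in SK-LC-3.

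A transfected microRNA lowers transcripts that match its seed, the bases near its start. Among 11051 words of 7 bases found in the probe sequences, the miR-342-3p seed match GTGTGAG had a mean log2 fold change of -0.11 over 88 probes, against 0.02 for the other probes, at percentile 0.0814 of the words. The mean was -0.11 on each slide, and with the replicate block 20 of the 88 were lower and 4 higher. The match to the other strand of the precursor, miR-342-5p GCACCCC, had a mean of 0.06 over 34 probes at percentile 93.4. These values are consistent with direct lowering of some transcripts by miR-342-3p. They cover the probe alone, which is a short part of each transcript, and 8 words, among them CGAGAAA, GGTTGAG, CATATTC and TATAGTA over 32 to 58 probes, had a lower mean than GTGTGAG. The words were also ranked by the distance of their mean from that of all probes, over a standard error from the SD of all probes. By this measure GTGTGAG ranked lowest of all (percentile 0.00905). The rank fixed beforehand was that of the mean alone.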
